A study of Mus musculus with 8 samples.

How the data were processed

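Single-nucleus Multiome libraries of day 24 mouse kidney progenitor assembloids were analysed from 4 barcode lists and 4 feature lists, 1 of each per replicate. Per the submitters' processing notes, the libraries were processed with Cell Ranger ARC 2.0.2 and STAR, and the genome build named is GRCm39. The deposited files used here give barcodes of nuclei, gene rows and peak positions, and no score or count was read from them, so peaks entered as present or absent. Peaks were listed separately for each library. Count matrices were not used here, so no expression value is reported and the sequencing depth is unknown.

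The peak positions fit GRCm38 and not the build named in the notes. Peaks reach position 195372029 on chromosome 1, which lies beyond the end of that chromosome in GRCm39. With gene positions of the GRCm38.p6 RefSeq table, a mean of 71.1% of genes had a peak within 1 kb of an end (SD 2.32, n = 4), against 35.9% when gene positions were moved by 10 kb and 35.1% when moved by 50 kb. All 21 chromosomes had more genes with a peak in place than moved by 10 kb. The RefSeq table was therefore used for gene positions, and only positions from the files are printed, read as BED intervals and counted from 1.

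Genes were protein-coding genes of that table with a single place on chromosomes 1 to 19, X or Y whose symbol is among the 32287 gene rows, 20655 in all. The table gives no strand or exons. A gene end was therefore used in place of the promoter. It means within 1 kb of either end of the gene, and the windows of 50 kb surround both ends. A gene-end peak may thus lie at the 3' end, and a promoter inside the gene is missed. Its presence or absence need not be that of a promoter peak. Peaks of the 4 libraries were merged where they overlapped by 1 bp. A distal region overlaps no gene end of a protein-coding or lncRNA gene. One feature line of batch 1 replicate 1 on chromosome 18 was empty, and 1 merged region there was left out.

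A list member counted as having a shared gene-end region when a merged region with peaks of all 4 libraries lay within 1 kb of either end. Because merged regions are wider than peaks, Cdx1 and Cdx2 count although not every library has its own peak within 1 kb. Synpo, Elf5, Neurog1, Hoxc4 and Hoxa13 do not count although each library has one, since these peaks fall in different regions. A count by own peaks is given among the alternatives. That version was by mistake the first to be tested, and it also called liver and gut genes. The use of merged regions of all 4 libraries, fixed beforehand, was then restored for the report. Lists were compared with 10000 random lists of the same size in a two-sided permutation test with Benjamini-Hochberg adjustment over 24 lists; the smallest p this can give is 0.0002. The planned matching on promoter CpG content and the planned motif counts were not run because no genome sequence was used here. Batch-only regions near lists were tested with a two-sided Fisher exact test, with Woolf 95% intervals of the odds ratio. Genes are not independent replicates in these tests.

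The 24 gene lists, the tests and the rule for named genes were fixed before the data were examined, but that plan used 5' gene ends. Because no strand was given, both gene ends replaced them in the tests on gene ends and distal regions and in the rule. The rule takes list members, with up to 6 members lacking a shared region named in list order and 2 to 4 having one, the 10 genes with most shared distal regions, the 10 clusters of shared regions, stitched at 10 kb, with the most covered base pairs, and the 10 genes per batch with most batch-only distal regions. Genes of the X and Y chromosomes and gene families named in the closing observations fall outside it. Some genes that the rule takes are not reported here by name, and the counts of lists include them. Alternatives were each library left out, peaks of 500 bp or more, equal numbers of peaks, 50% reciprocal overlap, other windows, regions of at least 2 libraries and the replicate block. Others were chosen after seeing the data: length-matched random lists, peaks anywhere in a gene, own peaks of each library, absence within 1 kb, and the batch tests of gene ends and families. Families were formed by a fixed pattern on symbols; a set of prefixes picked by hand after the data had been seen was tried earlier and is not reported.

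Barcodes shared between pairs of libraries numbered 135 to 177, a small part of the 9596 or more nuclei of a library, so no library appeared to be present in duplicate. Doublets were neither called nor removed here, and whether they were removed earlier is not given in the sources used here. The functions were tested on simulated data, where merged regions, overlaps and gene windows had 0 errors. In the permutation and Fisher exact tests, 2% of 200 unchanged gene lists and 2% of 200 unchanged region lists had p under 0.05. Of 200 region lists simulated with an odds ratio of 3, 98.5% were found. The highest odds ratio among the gene lists was 2.25, for liver and gut genes, and finding smaller ones was not tested. Random gene lists matched in length had medians of 70.7% (podocyte) to 74.2% (Hox groups 9 to 11) batch 2 only among their batch-only regions. Over all batch-only regions, 49155 of 73903 were batch 2 only. The 2% of simulated region lists therefore need not hold for regions near real genes in the Fisher exact test. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.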

Results

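Mouse kidney progenitor assembloids are cultured kidney-like structures assembled from progenitor cells. Those studied here carried a tdTomato reporter of Six2, a transcription factor of nephron progenitors, and a Venus reporter of Hoxb7, a gene of the ureteric bud lineage. They were collected at day 24 and profiled by single-nucleus Multiome, which measures RNA and open chromatin in the same nuclei. There were 2 batches with 2 replicates each, and each replicate had a gene expression library and an ATAC library, 8 samples in all. Batch and replicate number were the only differences named between them. The values used were the barcodes of nuclei and the positions of open-chromatin peaks. Peak heights and RNA counts were not analysed here, so a peak is present or absent in a library and its depth is unknown.

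Batch 1 held 9596 nuclei in replicate 1 and 10832 in replicate 2, and batch 2 held 10112 and 11376. On chromosomes 1 to 19, X and Y, batch 1 had 120745 and 124775 peaks, and batch 2 had 151056 and 148524. The mean was 122760 ± 2850 (SD, n = 2) in batch 1 and 149790 ± 1790 (SD, n = 2) in batch 2, a 1.22-fold difference that is larger than the spread within either batch. A two-sided exact permutation test gave p = 0.33, the smallest p that 2 libraries against 2 can reach. The labels do not say whether replicates came from separate cultures, so the spread between them may be technical. Median peak width lay between 864 and 872 bp in all 4 libraries.

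Shared open chromatin covered the most base pairs in clusters nearest Csrp1 and Irf2bpl and in the HoxA and HoxD clusters. Peaks of the 4 libraries merged into 216145 regions, and 68714 of these (31.8%) had a peak in every library. The cluster of shared regions with the most covered base pairs, on chromosome 1 from 135659246 to 135799796, held 33 regions and lay nearest Csrp1, which encodes a LIM-domain protein of the actin cytoskeleton. Next came a cluster of 30 regions on chromosome 12 from 86823639 to 86951194 nearest Irf2bpl. The HoxA cluster on chromosome 6 from 52150304 to 52248873 held 25 shared regions, and the HoxD cluster on chromosome 2 from 74647224 to 74763510 held 24. The remaining clusters among the 10 with the most covered base pairs lay nearest Cyp1b1, Socs3, Lhfpl2, Itga3, D630003M21Rik and Plekha6.

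Counted per gene, Csrp1 had the most shared distal regions within 50 kb of its ends, 26. Clmp, Cuedc1 and Col4a2, which encodes a basement membrane collagen chain, had 23 each, and Cyth3 had 22. Fbn1, which encodes the microfibril protein fibrillin, Nrp2, Tns3, Ergic1 and Fgf1 had 21 each. The mean over 20655 protein-coding genes was 3.66. A shared region lay at an end of 13488 of these genes (65.3%), and 4906 (23.8%) had no gene-end peak in any library. By library, 18.3% ± 0.462 of peaks (SD, n = 4) overlapped a gene end, 50.8% ± 2.00 lay elsewhere inside a gene and 30.9% ± 1.56 were intergenic. Gene ends took 26.9% of the regions shared by all 4 libraries.

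Which kidney cell programmes had open gene ends in every library was asked of 24 gene lists fixed before the data were examined. Either end of a gene counted and promoters inside a gene did not. A member without a shared region may therefore still have an open promoter, and a member with one may have it at the 3' end. All 8 ureteric tip genes had a shared region at a gene end, including Ret, the receptor that drives branching of the ureteric bud, and Wnt11 and Etv5. Among nephron progenitor genes 9 of 12 had one, including Six2, Eya1 and Gdnf, while Meox1, Crym and Uncx did not. Early nephron genes had one at 10 of 12 members, including Wnt4, Lhx1 and Pax8, and lacked one at Cdh6 and Pou3f3. Podocyte genes had one at 11 of 14, including Nphs1, which encodes a slit diaphragm protein, and Wt1, and lacked one at Synpo, Clic5 and Magi2. Synpo, and in the lists that follow Elf5, Neurog1, Hoxc4 and Hoxa13, had peaks at their gene ends in each of the 4 libraries, but these did not merge into 1 region common to all. Stromal genes had one at 12 of 13, with Ren1, the renin gene, as the exception. None of these lists passed the test against random lists of the same size. In the order given, random medians were 5, 8, 8, 9 and 9. The adjusted p in the two-sided permutation test was 0.197, 0.800, 0.434, 0.561 and 0.197. Even with all 8 members having a shared region, the ureteric tip list had an unadjusted p of 0.0656 in this permutation test. The test could therefore hardly call lists this short higher. Not passing does not show that their gene ends were open no more often than those of random lists.

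At Six2 a peak on chromosome 17 from 85687942 to 85688825 in batch 1 replicate 1 had counterparts in the other 3 libraries. At Wt1 the corresponding peak lay on chromosome 2 from 105126139 to 105126982, and at Ret on chromosome 6 from 118196711 to 118197512. These positions are the files' own, counted from 1, in GRCm38 coordinates.

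The 3 tubule lists had fewer members with a shared gene-end region than the median of random lists, and none passed the test. Of 14 proximal tubule genes 6 had one, among them Lrp2, which encodes the endocytic receptor megalin, and Slc34a1, a phosphate transporter. Hnf4a, Hnf4g, Cubn, Slc5a2, Slc22a8 and Pdzk1 were among those without. Of 10 loop of Henle genes 3 had one, Cldn10, Irx2 and Irx3, and Umod, Slc12a1, Kcnj1, Cldn16, Cldn19 and Irx1 were among those without. Of 11 distal and connecting tubule genes 4 had one, including Calb1 and Wnk4, and Slc12a3, Pvalb, Tfap2b, Trpv5, Trpm6 and Klk1 were among those without. Random lists of the same size had medians of 9, 7 and 7, and adjusted p in the two-sided permutation test was 0.282, 0.197 and 0.222 for these 3 lists. By own peaks, loop of Henle genes had a gene-end peak at 3 and 5 of 10 members in the batch 1 libraries, and at 8 and 10 in batch 2. Proximal tubule genes had 7 and 8 of 14 against 12 and 10, and distal and connecting tubule genes 5 and 6 of 11 against 8 and 7. Over all genes the share was 68.6% and 69.7% in batch 1, and 73.2% and 72.9% in batch 2.

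Collecting duct principal cell genes had a shared gene-end region at 10 of 15 members, including Aqp2, the vasopressin-regulated water channel, and Scnn1b, and lacked one at Aqp4, Avpr2, Elf5, Gata3 and Wnt9b. Intercalated cell genes had one at 3 of 8, including Slc26a4, and lacked one at Foxi1, Atp6v1g3, Slc4a1, Slc4a9 and Aqp6. Among cystic kidney disease genes 10 of 12 had one, including Pkd1 and Pkhd1, and Pkd2 was among those without. Injury and immediate early genes had one at 8 of 12, including Sox9 and Fos, and lacked one at Havcr1, Lcn2, Krt18 and Cdkn1a.

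Genes of other tissues varied. Endothelial genes had a shared gene-end region at 8 of 12, including Kdr and Flt1, and lacked one at Pecam1, Cdh5, Tie1 and Eng. Immune genes had one at 3 of 11, including Csf1r, and Ptprc, Tyrobp, Laptm5, C1qa, C1qb and Cx3cr1 were among those without. Erythroid genes had one at 2 of 7, including Klf1, and lacked one at Gata1, Hbb-bt, Hba-a1, Alas2 and Hemgn. Neuronal genes had one at 6 of 12, including Neurod1 and Sox1, and Neurog1, Olig2, Stmn2, Elavl3 and Dcx were among those without. Muscle genes had one at 4 of 11, including Des and Pax3, and Myod1, Myog, Myf5, Pax7, Actc1 and Myh3 were among those without. Liver and gut genes had one at 3 of 10, Apoa2, Cdx1 and Cdx2, and Alb, Afp, Fga, Fgb, Ahsg and Cps1 were among those without.

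Only the pluripotency and germline list passed the test on gene ends. Of its 9 genes only Dazl had a shared region, against a random median of 6 with a 95% range of 3 to 8, while Pou5f1, Nanog, Zfp42, Dppa3, Dppa4 and Dppa5a were among those without. The adjusted p was 0.048 in the two-sided permutation test with 10000 random lists, and 4 of the 24 lists had an unadjusted p under 0.05. This call was lost under 6 of the alternative settings, which include leaving out batch 1 replicate 1 (2 genes with a region, permutation test adjusted p = 0.126) and matching random lists on gene length (permutation test adjusted p = 0.0912). All 12 housekeeping genes, such as Actb and Gapdh, and all 10 cell cycle genes, such as Mki67 and Top2a, had a shared region, with adjusted p of 0.156 and 0.18 in the same permutation test. Complete lists thus did not pass, so the test had little room to call short lists higher.

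Hox genes of paralogue groups 1 to 4 had a shared gene-end region at 10 of 12 members, Hoxb1 and Hoxc4 being the exceptions. Groups 9 to 11, which include the kidney-patterning gene Hoxa11 and Hoxd11, had one at 9 of 10, Hoxd10 being the exception. Groups 12 to 13 had one at 2 of 6, Hoxc13 and Hoxd13, and lacked one at Hoxa13, Hoxb13, Hoxc12 and Hoxd12. None of these 3 lists passed the test.

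Podocyte genes had more distal regions around them than random lists did, with a mean of 7.57 shared distal regions within 50 kb, against a random median of 3.64 with a 95% range of 2 to 5.64. The adjusted p was 0.0096 in the two-sided permutation test over 24 lists, and 5 lists had an unadjusted p under 0.05. Wt1, the transcription factor gene of podocytes and nephron progenitors, had 19 such regions, Synpo 19, and Lmx1b, Plce1 and Col4a3 had 9 each. Means for Hox groups 1 to 4 (6.67), Hox groups 9 to 11 (6.1) and nephron progenitor genes (5.92) did not pass, with adjusted p of 0.103, 0.231 and 0.231 in the same permutation test. Cell cycle (5.9), injury and immediate early (5.58) and housekeeping genes (5.25) also lay above their random medians without passing. Erythroid, muscle, liver and gut, and pluripotency and germline genes lay below theirs. Podocyte genes were not tested against these lists. Both Hox lists and the injury and immediate early list also passed with random lists matched on gene length, nephron progenitor and stromal genes with a window of 20 kb, and Hox groups 1 to 4 with a window of 100 kb. Hox genes are neighbours and can count the same distal regions repeatedly. The range of random lists scattered over the genome may therefore be too narrow for them, and the effect of this was not tested. Neuronal genes had a mean of 1.75 and did not pass either.

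**Figure D1:**
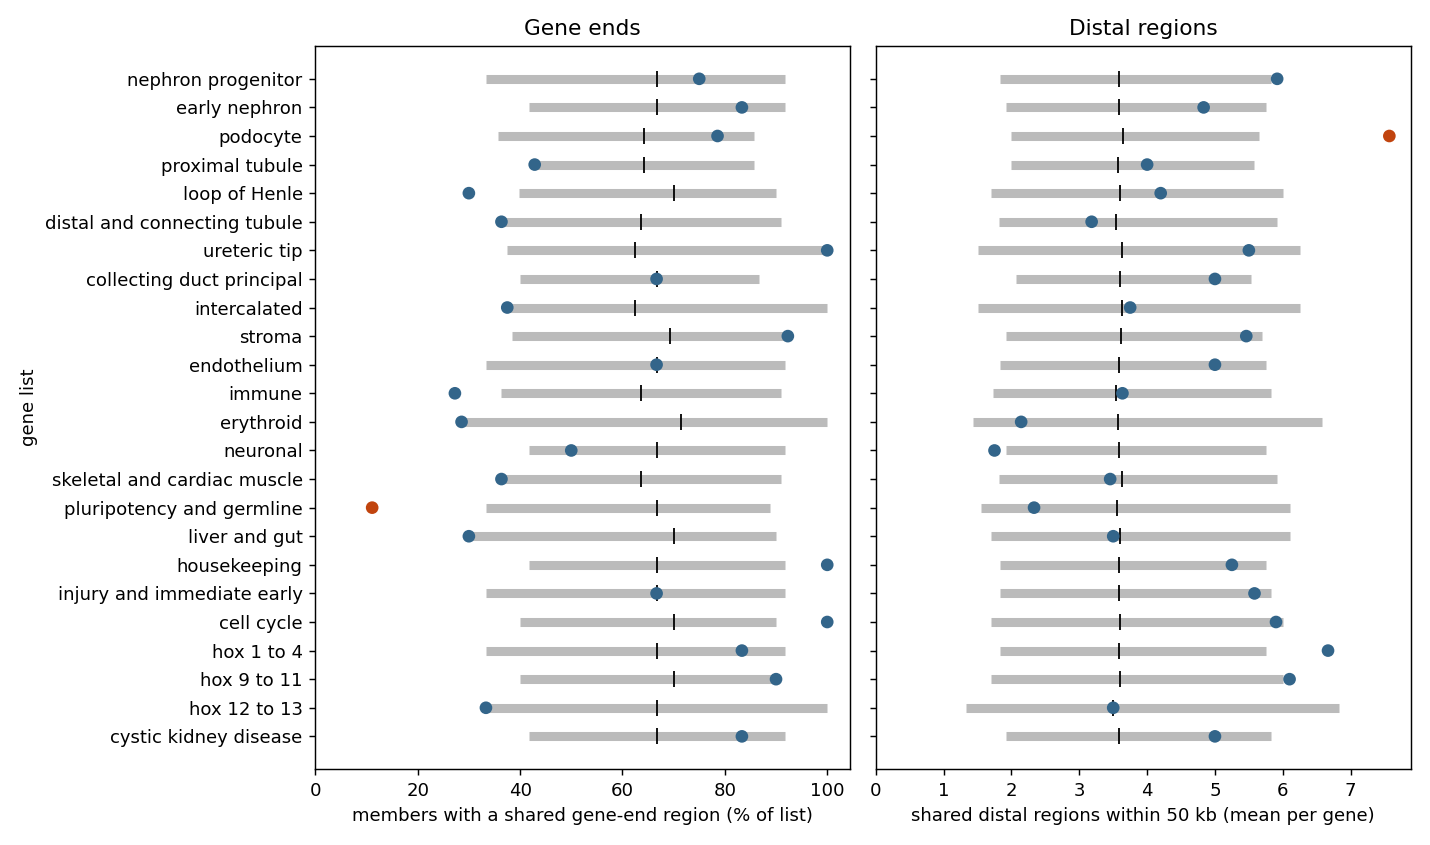
Each row is one of the 24 gene lists. The left panel plots the percent of members with a shared gene-end region, the right panel the mean number of shared distal regions within 50 kb per gene. Points are observed values, grey bars the 95% range of 10000 random lists and ticks their median, and orange marks the lists past 5% after adjustment, the pluripotency and germline list (1 of 9) on the left and the podocyte list (7.57) on the right.

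The batches differed widely in which regions had called peaks. A total of 49155 regions had peaks in both batch 2 libraries and in neither batch 1 library, and 24748 had the opposite pattern, 73903 together. With an equal number of peaks in each library these were 37243 and 32634. Without batch 1 replicate 2 the batch 1 only regions numbered 40992, since a peak in batch 1 replicate 1 alone then sufficed. Dividing the 4 libraries across batches gave 1727 such regions by replicate number and 1750 in the other crossed division. The Jaccard index of covered base pairs was 0.639 within batch 1 and 0.782 within batch 2, a mean of 0.710 ± 0.102 (SD, n = 2 pairs), against 0.376 ± 0.0285 (SD, n = 4 pairs) between batches. The batch division had the highest value of the 3 possible ones, an exact permutation p of 0.33, the smallest these libraries allow.

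**Figure D2:**
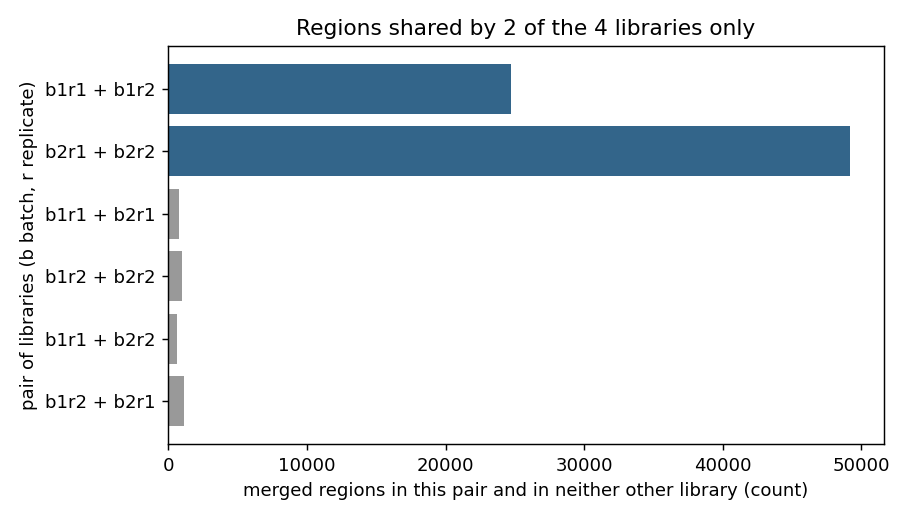
Bars give the number of merged regions found in both libraries of a pair and in neither other library, for the 6 pairs. The 2 batch pairs (blue) have 24748 and 49155 regions, and the 4 pairs that cross batches (grey) have between 651 and 1099.

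Grk3, which encodes a kinase that acts on G protein-coupled receptors, had the most distal regions seen in batch 1 only, 16, beside 2 seen in batch 2 only. Apba2 had 15 against 1, Cwc22 15 against 2, and Ptprb, a phosphatase gene of endothelium, 13 against 5. Atg7, Cldn10, Myo18b, Myrip and Nox3 had 11 in batch 1 only. Cldn10 also had 15 in batch 2 only, so a high count in one batch did not exclude the other. In batch 2 only, Myh9, which encodes nonmuscle myosin heavy chain, and Zhx2 had 19 each, beside 1 and 4 in batch 1 only. Ugt1a6a and Ugt1a8 also had 19 and Ugt1a6b and Ugt1a7c 18, but these glucuronosyltransferase genes are neighbours on chromosome 1 and share regions. Arhgef10 and Myo10 had 18, and Ank3 and 3110082I17Rik had 17, a count that further genes shared, the order among them being by symbol.

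Batch 2 only gene ends were found at 794 protein-coding genes and batch 1 only gene ends at 201. With the widest 120745 peaks of each library, which changes both the number and the widths of peaks, these turned to 661 genes in batch 2 only and 903 in batch 1 only. Batch 1 only gene ends numbered 304 without batch 1 replicate 1 and 326 without batch 1 replicate 2, as a peak in the remaining batch 1 library then sufficed. Among the listed tubule genes they were found in batch 2 only at Hnf4g, Cubn, Pdzk1, Umod, Kcnj1, Cldn19, Tfap2b and Trpm6, and in batch 1 only at Slc8a1, a sodium-calcium exchanger. Thus 8 of 35 tubule genes had a gene-end peak in both batch 2 libraries alone and 1 in both batch 1 libraries alone, and these counts were 7 and 2 with an equal number of peaks. They were 12 and 2 without batch 1 replicate 2, when only batch 1 replicate 1 had to lack or hold the peak. For Umod, which encodes uromodulin, the peak lay on chromosome 7 from 119479071 to 119479965 in batch 2 replicate 1, and for Cubn, the endocytic receptor cubilin, on chromosome 2 from 13491538 to 13492454. Outside the tubule lists, Pou3f3, Cdh6, Crym, Tie1, Lcn2, Fga, Hoxd10 and Hoxc12 were among the listed genes with a gene-end peak in batch 2 only, and Cdh5 and Cdkn1a had one in batch 1 only. Which of these peaks lie at a promoter and which at the other end of the gene is not known. No list passed a two-sided Fisher exact test on the counts of batch-only gene ends, which was chosen after the data had been seen. The lowest adjusted p was 0.266 for loop of Henle genes (3 of 10) in that exact test.

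Within 50 kb of list members, batch 2 only and batch 1 only regions numbered 80 and 22 near proximal tubule genes, with an odds ratio against all other such regions of 1.80 (95% interval 1.13 to 2.88). They numbered 50 and 12 near distal and connecting tubule genes (odds ratio 2.035, 1.095 to 3.781). Near housekeeping genes they numbered 49 and 12 (odds ratio 1.995, 1.072 to 3.71, but 1.05 with an equal number of peaks). Liver and gut genes had 33 and 7 (odds ratio 2.25, 1.02 to 4.97). Near cell cycle genes they numbered 31 and 28 (odds ratio 0.556, 0.335 to 0.923). None of the 24 lists passed, the lowest adjusted p being 0.162 in a two-sided Fisher exact test, and these 5 had an unadjusted p under 0.05. Distal and connecting tubule genes passed without batch 1 replicate 1 (odds ratio 2.37, Fisher exact test adjusted p = 0.0433). Regions are not independent replicates, and these intervals cover these libraries only.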

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

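Peaks on unplaced scaffolds were left out of the comparisons and are present in each library, above the limit that a count of 0 allows. They numbered 50 in batch 1 replicate 1, 44 in batch 1 replicate 2, 48 in batch 2 replicate 1 and 51 in batch 2 replicate 2. No explanation was tested for them.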

How the results depend on the processing

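The length-matched lists, peaks anywhere in a gene, own peaks of each library, absence within 1 kb and the alternatives of the list test on batch-only regions (other than its windows) were chosen after seeing the data. The podocyte call on distal regions held under each of its 10 alternatives, and the division by batch kept its direction throughout. The number of lists past the test on gene ends, 1 in the report, was 0 with peaks of 500 bp or more, with an equal number of peaks, with regions of at least 2 libraries, with random lists matched on gene length and with a peak anywhere in the gene, 3 with gene ends 500 bp either side, and 2 with an own peak of each library at the gene end, where liver and gut genes joined (1 of 10). It ranged from 0 to 1 with single libraries left out. The number past the test on distal regions, 1 in the report, was 3 with a window of 20 kb, 2 with a window of 100 kb and 4 with random lists matched on gene length. Lists past the test on batch-only regions ranged from 0 to 1 with single libraries left out, being 1 without batch 1 replicate 1. Batch 1 only regions ranged from 27212 to 40992 with single libraries left out, the highest without batch 1 replicate 2. Leaving out a library asks for presence or absence of a peak in fewer libraries, so these counts rise by definition. Gene ends took 24.1% of peaks with 2 kb either side, by construction. For the others the cause was not tested.

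With the replicate block the log2 ratio of peak numbers was 0.29, equal to the unblocked value because the design is balanced, and deviations of equally numbered replicates had a correlation of 0.000553 across regions, so the numbers gave no sign of pairing. No blocked value can be had for batch-only regions or the overlap index. Matching on CpG content, a single 5' gene end and all motif alternatives were not run. Without peak heights, a peak missing from a library may lie just under the calling threshold, which no alternative here tests.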

Other observations

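Tests on the number of called peaks for the sex chromosomes and for the batch division, and the test on cells, were chosen after the results had been seen, as were the families. The batches differed on the sex chromosomes. Both batch 1 libraries had a peak at an end of each of the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y, and neither batch 2 library had one. Both batch 2 libraries had a peak at an end of Xist, the RNA gene that silences an X chromosome in female cells, and of its antisense partner Tsix, and neither batch 1 library did. Ftx, Jpx, Kdm5c, Ddx3x and Eif2s3x had one in all 4 libraries and Kdm6a in none. These genes, other than Xist, were chosen after their values were seen. Y peaks numbered 44 and 42 in batch 1 and 25 and 25 in batch 2, and X peaks 1885 and 1884 against 2732 and 2672. Against autosomes, the odds of a batch-only region being from batch 2 were 1.94 on X (95% interval 1.68 to 2.24) and 0.175 on Y (0.0838 to 0.367).

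A larger number of peaks called in batch 2 argues for more Y peaks there, but the highest batch 2 number minus the lowest batch 1 number was -17. A candidate explanation is a larger share of female nuclei in batch 2: the number of libraries with a peak at an end of Xist was higher by 2 in batch 2, as written down before Xist was looked at. The labels give no sex, and the 25 Y peaks left in batch 2 were not explored, so this stays a hypothesis that batch and sex of the source may be confounded.

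Batch 2 only regions were more frequent near the 3 tubule lists combined, 199 against 62 in batch 1 only, an odds ratio of 1.61 (95% interval 1.21 to 2.14). The lists were combined after the data had been seen, and loop of Henle genes alone had 69 against 28, an odds ratio of 1.23 (0.794 to 1.90). With 120745 peaks in every library the odds ratio was 1.64 and the lower end of its interval 1.24, so the larger number of peaks in batch 2 does not account for it, as far as keeping the widest peaks equalises the libraries. A tilt of batch 2 only regions toward genes in general stays open. Among random gene lists of the same lengths, a share of 0.0939 (one-sided permutation test) reached the tubule share of 76.6%, whose random median was 71.7%. This share counts a region again for each gene it lies near, in the observed and the random lists alike, which gives 203 regions against 62. A difference between tubule genes and other genes is therefore not shown.

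Batch-only regions were also tested near 359 families of genes formed by symbol, of which 28 passed a two-sided Fisher exact test for batch 2 after adjustment and 0 for batch 1, with 3 families leaning to batch 1 at an unadjusted p under 0.05. The lowest adjusted p, 8.49e-05 in that exact test, belonged to the Rnf ring finger genes (397 regions in batch 2 only and 119 in batch 1 only near 80 genes). These tests compare with all other batch-only regions, not with other genes. Random lists matched in length to the 24 gene lists already had medians of 70.7% to 74.2% batch 2 only among their batch-only regions, and 0 of the 24 lists passed against them in the permutation test, with 2 at an unadjusted p under 0.05. The Wdr, Dusp, Bcl2 and Slc22 families also passed. Members of the Ugt1 family are neighbours and count largely the same 32 regions. Gene ends took 10.1% of batch 2 only and 7.29% of batch 1 only regions, and 31.2% and 41.5% were intergenic. With an equal number of peaks, genes with batch 2 only gene ends (661) were fewer than those with batch 1 only gene ends (903), and the families were not tested in that setting.

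For the division of the peak sets by batch, more peaks called in batch 2 cannot be the whole cause. Regions found in batch 1 only numbered 24748, against at most 1099 in a pair that crosses batches. Peaks at Kdm5d, Uty, Ddx3y and Eif2s3y in batch 1 alone, and at Xist and Tsix in batch 2 alone, point to nuclei of different sex make-up. Most batch-only regions lay on autosomes, 48234 of 49155 in batch 2 only and 24483 of 24748 in batch 1 only. Regions on X and Y themselves thus make up little of the division. How much of the autosomal part follows from sex make-up was not tested. Whether the cells also differed in type cannot be told apart from other batch differences. The 0.334 gap in Jaccard index within minus between batches would follow from either, and cell types were not analysed here.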
